A study of Homo sapiens with 6 samples.

How the data were processed

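RNA was sequenced in 6 libraries of human dermal lymphatic endothelial cells, the cells that line skin lymphatic vessels. According to the labels, the cells had been grown with VEGF-C, were lifted with trypsin and were seeded on plates coated with a Notch ligand or with the Fc control protein for 6 h. Titles, treatment labels and the design text name the ligand as JAG1, whereas the treatment protocol in the labels names DLL4 for the coated plates. The groups here follow the titles, with 3 JAG1 and 3 Fc libraries, and the conflict was not resolved. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

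The deposited table holds raw counts per gene for 56505 genes in the 6 libraries, in the column layout of featureCounts per the file headers. The submitters' processing notes name STAR 2.5.0a, featureCounts 1.5.2, DESeq2 1.18.1 and the GRCh38 build, without saying which step each served. The strand setting and the annotation release are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner therefore cannot be told apart, and such partners are pointed out beside the genes they concern. How reads that matched several places were counted is also not given, so near-identical copies may share or lose reads. Every column of per-sample values was matched to a sample by its name. Gene names and positions are those of the deposited table. Gene types and identifiers were looked up by symbol in GENCODE 29, where 66.07% of the table's symbols were found; the types served only the rule for naming genes. The genes listed under newer names as DEPP1, CCN1 and CCN2 appear in the table as C10orf10, CYR61 and CTGF.

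Total counts ran from 22182026 to 29646392 per library, and a floor of 3 counts corresponded to 0.101 to 0.135 CPM (counts scaled to the library total). Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 3.33 (Fc replicates 1 and 2), so none was treated as a library deposited more than once.

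Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 14838 genes. Libraries were scaled by TMM, and JAG1 was tested against Fc with the quasi-likelihood test and Benjamini-Hochberg adjustment, with the group as the single term. An adjusted p under 0.05 was a call. The standard error of a log2 fold change was its size divided by the square root of the F statistic, and levels are given as CPM, counts scaled by the TMM-adjusted library total. Fold changes came from edgeR with its default prior count. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists. Each list's calls were also counted with p-values adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

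The comparison, the lists, the alternatives and the rule for naming genes were set before the data were examined. The lists covered Notch targets and Notch components, lymphatic, blood vascular, arterial and venous endothelial genes, tip cell genes and junctions. They also covered adhesion molecules and chemokines, NF-kB, interferon, immediate early, ATF4 and heat shock genes, both cell cycle phases, cholesterol synthesis, glycolysis, hypoxia and ribosome biogenesis. The remaining lists were matrix, integrins, TGF-beta and BMP, mesenchymal transition, VEGF receptor signalling and guidance genes, fibroblast, pericyte, keratinocyte and leukocyte markers, and the mitochondrial genome. Named genes were the 12 largest rises and 12 largest falls among called protein-coding genes with a mean of at least 1 CPM and no overlap between groups. Up to 4 members per list with the smallest adjusted p were added, and a fixed set of Notch and endothelial genes. Some genes that the rule names are not reported here. Other called genes named in the text were chosen after their values were seen.

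The alternatives were DESeq2's median-of-ratios factors in the same edgeR test, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean of at least 1 CPM, a replicate block, an estimated correlation for the lists and leaving out each library in turn. A version with all libraries thinned to equal depth was added after seeing the data. The procedure was tested on simulated data for 14838 genes with the real means, library sizes and dispersions and 200 changed genes per set. The number of simulated sets was raised from 1 to 10 after the result of a single set had been seen. Over the 10 sets, 69.0% of the 1.5-fold, 84.8% of the 2-fold and 95.5% of the 4-fold changes were recovered. Over all 10 sets together 6.37% of calls were false, above the nominal 5%, with 1.79% to 9.73% in single sets. Genes on the Y chromosome and those that mark X inactivation were tested but are not reported.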

Results

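Human dermal lymphatic endothelial cells were profiled by bulk RNA sequencing 6 h after seeding on plates coated with JAG1, a ligand of Notch receptors, or with the Fc control protein. There were 3 libraries per group. The labels conflict on the ligand, since the treatment protocol names DLL4 where the titles and the design text name JAG1, and the groups are called by their titles throughout. Total counts were 29646392, 27048243 and 25274454 in Fc replicates 1 to 3 and 23410281, 22182026 and 23759309 in JAG1 replicates 1 to 3. Every Fc library was thus deeper than every JAG1 library. Fc replicate 3 stood apart from the rest, at -26.7 on the first principal component (26.2% of the variance) against -1.58 to 16.96 in the other libraries. That library also had the highest share of mitochondrial ribosomal RNA, 0.960% of counts against 0.539% to 0.648% elsewhere.

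The comparison asked how lymphatic endothelial cells respond to JAG1 through Notch. Genes for leukocyte adhesion and recruitment rose on JAG1, led by SELE, the endothelial adhesion molecule E-selectin, which went from 1.63 ± 0.31 to 24.5 ± 5.4 CPM (SD, n = 3 each). The chemokines CX3CL1, CXCL1, CCL2 and CXCL8 and the cytokine genes CSF2 and LTB rose with it. Genes of the NF-kB pathway, which controls inflammatory transcription, rose too, among them TRAF1, SOD2, TNFAIP2 and IRF1. Keratin genes of basal and activated keratinocytes, at low levels, and 7 genes of the mitochondrial genome fell. Whether the keratin RNA came from the endothelial cells or from a few keratinocytes was left undecided. Canonical Notch target genes such as HES1, HEY1, HES4 and NRARP did not pass the test in either direction.

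Of 14838 genes tested, 83 were called higher and 17 lower on JAG1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), which is 0.674% of the genes. At least a 2-fold difference was found for 20 of the higher and 4 of the lower genes, and 45 and 13 differed by less than 1.5-fold. All 100 had groups that did not overlap, as did 1978 of the tested genes (13.3%, where chance gives 10%). At an unadjusted p under 0.05 there were 1020 genes, with 742 expected if nothing changed. Leaving out single libraries gave 45 to 138 higher and 5 to 35 lower genes. The counts were 45 and 5 without JAG1 replicate 3, 49 and 6 without JAG1 replicate 1, 52 and 13 without Fc replicate 1, 64 and 11 without Fc replicate 2, and 138 and 35 without Fc replicate 3.

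SELE (chromosome 1, 169722641 to 169764705, GRCh38) rose by 3.92 ± 0.18 on the log2 scale (SE), a 15.1-fold rise (adjusted p = 2.88e-07). CSF2, the gene of the myeloid growth factor GM-CSF (chromosome 5, 132073790 to 132076170), had the largest estimate, 4.11 ± 0.38 (SE), but from a mean of 0.130 CPM in Fc (adjusted p = 0.000123). CX3CL1, the membrane-bound chemokine fractalkine (chromosome 16, 57372458 to 57385048), rose 5.58-fold from 4.84 ± 0.75 to 27.1 ± 5.0 CPM (SD, n = 3 each; adjusted p = 1.49e-06). LTB, which encodes lymphotoxin beta (chromosome 6, 31580525 to 31582522), rose 5.29-fold (adjusted p = 2.88e-07). CCL2, a monocyte chemokine (chromosome 17, 34255218 to 34257203), rose 3.25-fold from 31.8 ± 5.7 to 104 ± 2.1 CPM (SD, n = 3 each; adjusted p = 1.49e-06). The neutrophil chemokines CXCL1 and CXCL8 rose 6.10-fold and 3.08-fold. STUM rose 7.16-fold, ANO9 2.88-fold and RND1 2.98-fold. ICOSLG, a ligand for T cell costimulation, rose 4.40-fold (adjusted p = 0.0134) and NEURL3 2.505-fold (adjusted p = 0.0199). These last calls were lost without single libraries. ICOSLG lost its call without JAG1 replicate 3 (adjusted p = 0.104), JAG1 replicate 1 or Fc replicate 1. NEURL3 lost its call without any library except Fc replicate 3, at adjusted p of up to 0.147. Over all 12 alternatives, ICOSLG lost the call in 4, at adjusted p of up to 0.121, and NEURL3 in 6.

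Among the adhesion molecules and chemokines, 9 of 15 tested members rose, and 11 rose when adjusted over the list alone. Besides SELE, CX3CL1, CCL2, CXCL1, CXCL8 and CSF2, these were CSF3, CXCL2 and ICAM1, an adhesion molecule for leukocytes, which rose 2.14-fold (adjusted p = 2.04e-05) and overlaps an antisense gene. The list was called higher by camera (adjusted p = 1.65e-23) but not once its correlation was estimated (adjusted p = 0.0748 with an estimated correlation). Of 20 tested NF-kB response genes, 13 rose and all 20 had positive fold changes; 18 rose when adjusted over the list alone. TRAF1, a signalling adaptor of TNF receptors, rose by 1.23 ± 0.08 on the log2 scale (SE; adjusted p = 5.68e-06). SOD2, the mitochondrial superoxide dismutase, rose by 0.87 ± 0.05 (SE) from 385 ± 12 to 705 ± 28 CPM (SD, n = 3 each), with the antisense partners ACAT2 and WTAP as a limit. TNFAIP2 rose by 0.80 ± 0.08 and IRF1, which has the antisense partner C5orf56, by 0.67 ± 0.06 (SE). The inhibitor genes NFKBIA (0.57) and TNFAIP3 (0.38, overlapping an antisense gene) and the subunit genes RELB (0.44) and NFKB2 (0.38) rose less on the log2 scale. The NF-kB list was called higher (adjusted p = 2.16e-29), and this call too was lost at adjusted p = 0.0748 with an estimated correlation.

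**Figure D1:**
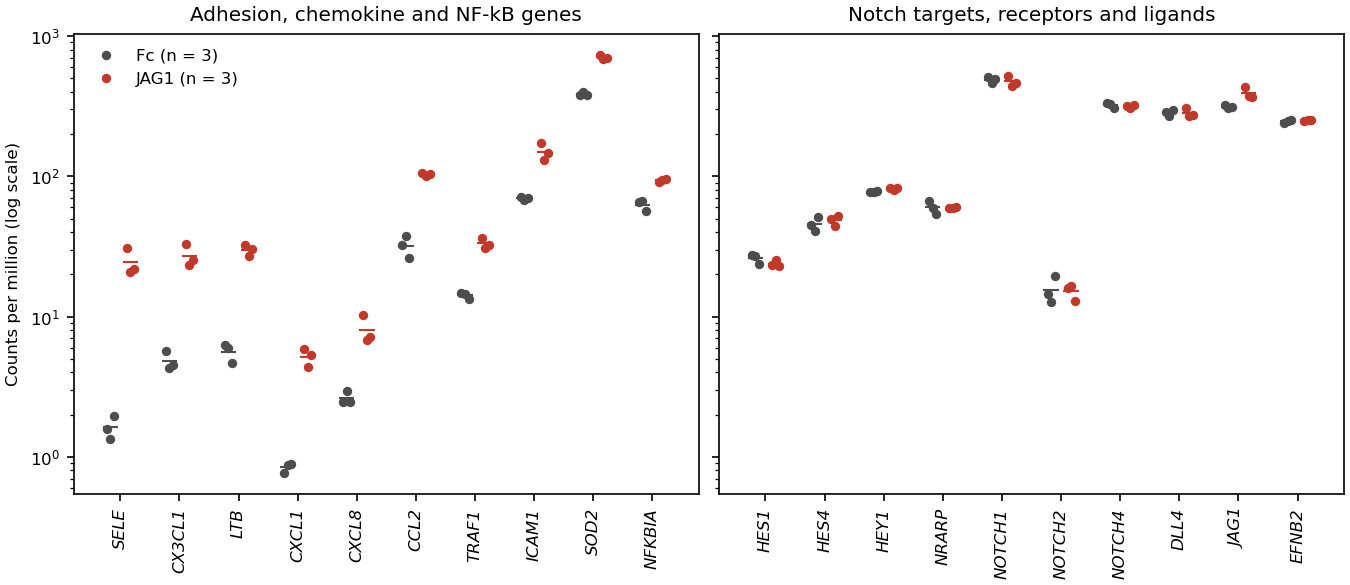
Levels in CPM on a log axis for each of 3 Fc and 3 JAG1 libraries, with a line at the group mean. All 10 genes of the left panel were called and, like every called higher gene, lay higher in every JAG1 library than in any Fc library. In the right panel JAG1 is the single gene called, and HEY1 also lay higher in every JAG1 library.

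None of 12 tested canonical Notch targets was called by edgeR, and DESeq2 and limma-voom called 0 as well. At an unadjusted p under 0.05 there were 2, and 1 was higher when adjusted over the list alone. HES1, the gene of a transcriptional repressor that Notch activates in many cells, was at 26.2 ± 2.1 in Fc and 23.8 ± 1.2 CPM in JAG1 (SD, n = 3 each), a log2 difference of -0.14 (95% interval -0.31 to 0.03). The interval was -0.03 to 0.19 for HEY1, -0.09 to 0.29 for HES4 and -0.17 to 0.14 for NRARP. The smallest adjusted p belonged to BMF, at 0.23 (adjusted p = 0.270), and HES2 and CCND1, which has the antisense partner ORAOV1, were at -0.18 and -0.14. HEY2 lay at 3 to 11 counts per library, too few to test, and HEYL and NOTCH3 lay near 1 CPM. The list as a whole was not called (adjusted p = 0.886). Among 31 Notch receptors, ligands and pathway components, the ligand gene JAG1 rose by 0.32 ± 0.06 on the log2 scale (SE; adjusted p = 0.0451), and 1 rose when adjusted over the list alone. The JAG1 call was lost in 7 of 12 alternatives. Among them were median-of-ratios factors (adjusted p = 0.0512) and leaving out any single library except Fc replicate 3, at up to 0.226 without JAG1 replicate 1. NOTCH1, NOTCH2, NOTCH4, which overlaps GPSM3, and DLL4 differed by -0.03, -0.03, -0.03 and -0.00069, and JAG2, PSEN2 and DTX4, with the antisense partner MPEG1, were at -0.12, 0.28 and 0.37. That list was not called (adjusted p = 0.971).

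**Figure D2:**
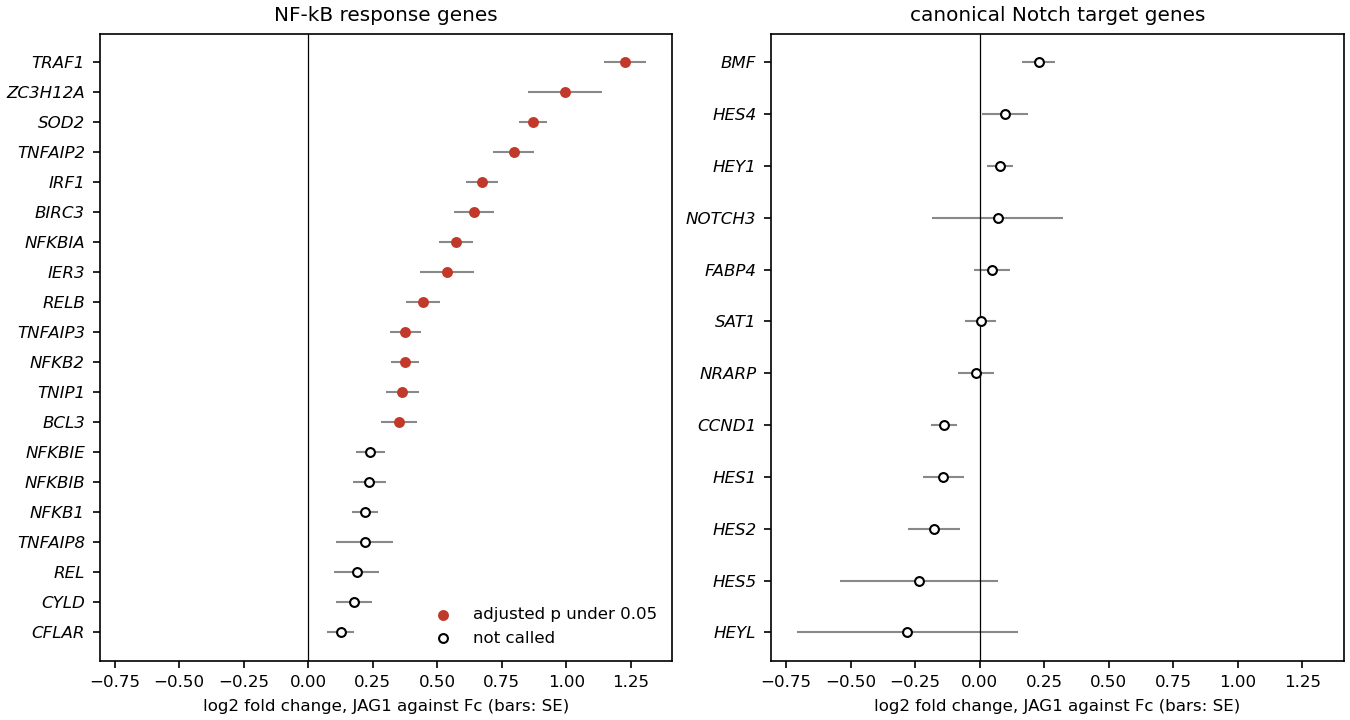
Log2 fold change of JAG1 against Fc for each tested member of the NF-kB and canonical Notch target lists, with bars of 1 SE and filled points for adjusted p under 0.05. The 20 NF-kB genes all lie above 0 and 13 are called, while the 12 Notch targets lie on both sides of 0 and 0 are called.

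Lymphatic endothelial identity genes did not pass the test, with 0 of 24 called by edgeR, DESeq2 or limma-voom and 3 at an unadjusted p under 0.05. The transcription factor PROX1, which has an antisense partner, was at -0.19 on the log2 scale, MAF at -0.21, LYVE1 at -0.15, PDPN at 0.12, FLT4, the VEGF-C receptor gene, at -0.03 and NR2F2 at -0.01. Adjusted over the list alone, 1 was lower. CCL21 had 0 counts in 5 libraries and 2 in 1 JAG1 library, and was not tested. Of blood vascular markers 1 of 19 rose (also 1 adjusted over the list alone) and of venous markers 1 of 11 (also 1), ICAM1 in both. SOX7 (0.19), NRP1 (-0.16, antisense partner), CXCR4 (0.13), CLU (-0.23), NT5E (-0.11) and NRP2 (-0.03, antisense partner) did not pass. Of arterial markers 1 of 17 rose, JAG1, and 3 higher and 1 lower were counted when adjusted over the list alone, where C10orf10 (0.28, antisense partner RASSF4) and BMX (0.22) were higher besides JAG1. EFNB2 was at 0.02 and UNC5B at -0.07. Tip cell genes (0 of 21; 4 higher adjusted over the list alone) were led by PDGFB (0.21), COTL1 (0.18), ODC1 (0.20) and PGF (0.15), and KDR was at -0.06. Junction genes (0 of 21; 1 higher adjusted over the list alone) were led by CLDN5 (0.25), GJA1 (-0.13), TJP1 (-0.08) and MARVELD2 (-0.39), with CDH5 at 0.02 and PECAM1 at -0.03. None of these lists was called (adjusted p = 0.597 for lymphatic, 0.886 for blood vascular, 0.938 for venous, 0.274 for arterial, 0.124 for tip cell and 0.788 for junction genes).

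Keratinocyte markers fell on JAG1, with 4 of 10 tested members called lower and 5 lower and 1 higher when adjusted over the list alone. KRT14 and KRT5, the keratin pair of basal keratinocytes, fell by 4.71 ± 0.62 and by 3.33 ± 0.31 on the log2 scale (SE; adjusted p = 0.00193 and 0.000123). KRT6A fell by 3.44 ± 0.42 and KRT17 by 4.19 ± 0.61 (SE; adjusted p = 0.00101 and 0.00401). Without JAG1 replicate 3 the fitted values were -9.13 for KRT14 and -5.95 for KRT17, and without any other library they lay between -4.96 and -4.15 and between -4.47 and -3.65. The value of -9.13 depends on the prior count, because KRT14 had 0 counts in both JAG1 libraries that remained. Levels were low: KRT5 had 90, 107 and 122 counts in Fc replicates 1 to 3 and 10, 5 and 12 in JAG1 replicates 1 to 3, and KRT14 had 52, 90 and 81 against 0, 0 and 7. KRT6A, KRT14 and KRT17 have similar copies or pseudogenes that could share reads. DESeq2 did not call KRT14 (adjusted p = 0.112). The list was called lower (adjusted p = 5.80e-06; adjusted p = 0.120 with an estimated correlation). Of the mitochondrial genome, 7 of 13 genes fell, 12 when adjusted over the list alone, and all 13 had negative fold changes. MT-ATP6, a subunit gene of ATP synthase, fell by 0.47 ± 0.06 on the log2 scale (SE; adjusted p = 0.00199), MT-ND4L by 0.48, MT-ND4 by 0.38, MT-CYB by 0.37 and MT-ND2 by 0.35. MT-ATP8 fell by 0.54, but it overlaps MT-ATP6, which also overlaps MT-CO3, as MT-ND4L overlaps MT-ND4. The list was called lower (adjusted p = 8.37e-16; adjusted p = 0.214 with an estimated correlation). The mitochondrial share was 3.77% ± 0.19 of counts in Fc and 2.97% ± 0.18 in JAG1 (SD, n = 3 each). All named mitochondrial calls except MT-ATP6 were lost without JAG1 replicate 1 or 3, at adjusted p of up to 0.203 for MT-CYB. Over all 12 alternatives, MT-ATP8 and MT-ND4L lost the call in 3, MT-CYB in 4, and MT-ND4 and MT-ND2 in 5.

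**Figure D3:**
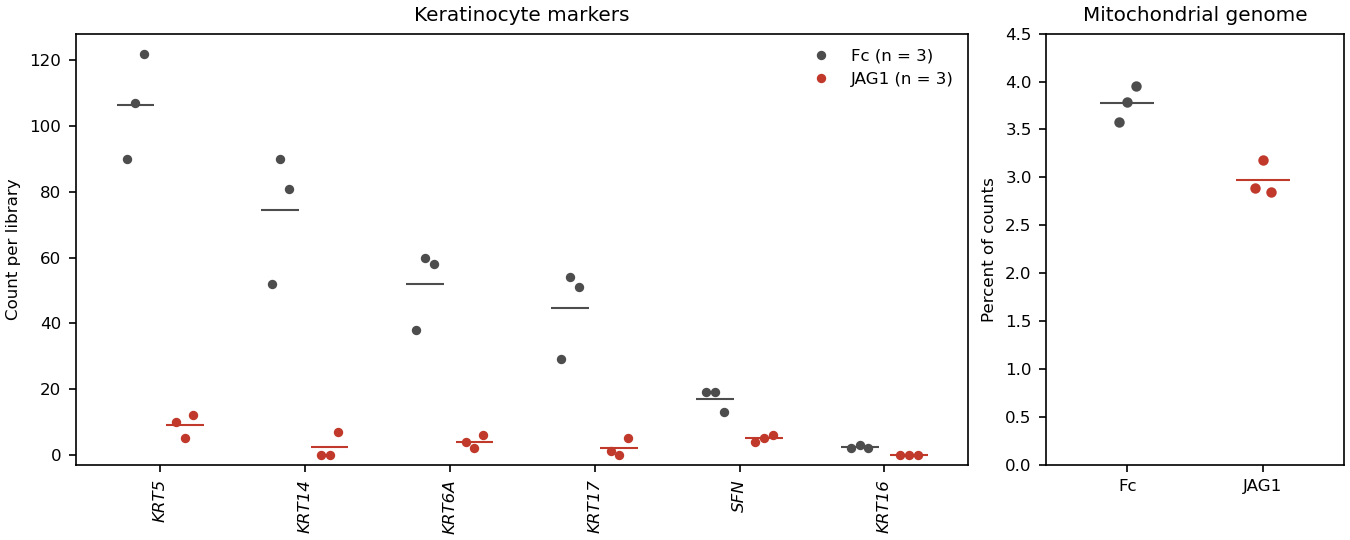
Left, counts per library for 6 keratinocyte markers in 3 Fc and 3 JAG1 libraries, with a line at the mean. Right, percent of counts from the mitochondrial genome in the same libraries. The keratins KRT5, KRT14, KRT6A and KRT17 lie higher in every Fc library, and mitochondrial shares range from 3.57% to 3.96% in Fc and from 2.85% to 3.18% in JAG1.

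Other large falls were ADCY1, an adenylyl cyclase gene, by 0.53 on the log2 scale (adjusted p = 0.0369), CH25H, the enzyme that makes 25-hydroxycholesterol, by 0.41 (adjusted p = 0.0262), and TRIL, with an antisense partner, by 0.34 (adjusted p = 0.0383). These 3 calls were lost on leaving out any JAG1 library or Fc replicate 1, at adjusted p of up to 0.231, 0.196 and 0.267. The CH25H call was also lost without Fc replicate 2. Over all 12 alternatives, ADCY1 lost the call in 5, CH25H in 6 and TRIL in 5, at adjusted p of up to 0.239, 0.198 and 0.267. Marker lists of 3 other cell types had no called member. Fibroblast genes (0 of 9; 0 adjusted over the list alone) included FBLN1 (-0.34), COL3A1 (0.17), PDGFRB (-0.44) and FBLN2 (0.32), and the list was not called (adjusted p = 0.938), except without JAG1 replicate 3 (0.0418). Pericyte genes (0 of 8; 0 adjusted over the list alone) included MYH11 (0.49), TAGLN (-0.34) and MCAM (0.08), all with antisense partners, and the list was not called (adjusted p = 0.918). Leukocyte genes (0 of 5; 0 adjusted over the list alone) included CORO1A (-0.25), CD14 (0.23), CSF1R (-0.11) and CD74 (0.04), and the list was not called (adjusted p = 0.938).

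Among stress and signalling genes, 3 lists were called higher without a single member called. ATF4 and unfolded protein response genes (0 of 25; 1 higher adjusted over the list alone) had a median log2 difference of 0.08, led by CHAC1 (0.48), ATF3 (0.34), ATF5 (0.21, overlapping IL4I1 and NUP62) and DNAJB9 (0.17, overlapping PNPLA8 and THAP5). That list was called (adjusted p = 0.00174; adjusted p = 0.120 with an estimated correlation). Immediate early genes (0 of 25; 2 higher adjusted over the list alone) were led by JUNB (0.33, antisense partner HOOK2), IER5 (0.21), ATF3 and CYR61 (0.19). That list was called (adjusted p = 0.0141; adjusted p = 0.647 with an estimated correlation), but not without Fc replicate 3 (0.363) or JAG1 replicate 3 (0.0806). Interferon response genes (0 of 26; 2 higher adjusted over the list alone) were led by IFIH1 (0.36; adjusted p = 0.0507), ISG20 (0.21), IFIT2 (0.29, antisense partner LIPA) and ISG15 (0.24). That list was called (adjusted p = 0.0402; adjusted p = 0.774 with an estimated correlation). It was not called with the replicate block or without Fc replicate 1 (0.146) or Fc replicate 3 (0.297), and it turned lower without JAG1 replicate 3 (0.988). Cholesterol biosynthesis genes (0 of 25; 0 adjusted over the list alone) were called lower as a list (adjusted p = 0.0339; adjusted p = 0.221 with an estimated correlation), with HMGCS1 at -0.18 and STARD4 at -0.22, both with antisense partners, and MSMO1 at -0.16. That call was also lost with the replicate block, without Fc replicate 1 (0.159) and without JAG1 replicate 1, 2 or 3 (0.123, 0.100 and 0.0550). Heat shock genes (0 of 17; 3 higher adjusted over the list alone), with CDKN1A (0.22), HMOX1 (0.20), DNAJA1 (0.16) and HSPA1A (0.17, with the near-identical copy HSPA1B), were not called (adjusted p = 0.124).

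The extracellular matrix list had 1 of 30 genes called higher, and 2 when adjusted over the list alone. MMP10 (0.43), MMP1 (0.24, antisense partner WTAPP1) and LOXL2 (0.15, overlapping ENTPD4) did not pass. Of TGF-beta and BMP response genes, 2 of 23 rose, among them BMP2 (0.32; adjusted p = 0.0494), and 4 when adjusted over the list alone, with TGFB2 at 0.61 (adjusted p = 0.0583) and ID2, which has an antisense partner, at 0.47. The BMP2 call was lost in 9 of 12 alternatives, at adjusted p of up to 0.316 (without JAG1 replicate 1). Of VEGF receptor and MAPK feedback genes, 1 of 22 rose, RCAN1, a calcineurin regulator gene (0.40, adjusted p = 0.00255). Adjusted over the list alone 1 rose, with VEGFC at 0.47. The RCAN1 call was lost in 1 of 12 alternatives (adjusted p = 0.06125). These lists were not called (adjusted p = 0.124 for matrix, 0.124 for TGF-beta and 0.886 for VEGF).

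The remaining lists had 0 called genes each and were not called. Adjusted over the list alone, glycolysis had 1 lower gene and the others had 0. They were G1/S genes (30; adjusted p = 0.736; CDC6 -0.32, PRIM1 -0.44, CHAF1B 0.28 and FEN1 0.12, of which all but CDC6 overlap other genes) and G2/M genes (30; 0.660; TOP2A -0.17, AURKB 0.24, ASPM -0.17 and BUB1 0.17). Glycolysis (21; adjusted p = 0.172) had SLC2A3 (-0.27), LDHA (-0.16), PFKFB4 (-0.23) and HK1 (-0.08), and was called lower without Fc replicate 2 (0.0342). Hypoxia genes (17; adjusted p = 0.938) had DDIT4 (0.20), STC2 (0.22) and P4HA2 (0.11). Ribosome biogenesis (24; adjusted p = 0.124) had UTP20 (-0.18), NOP58 (-0.13), POLR1A (-0.14) and NOP2 (-0.09). Integrins (24; adjusted p = 0.515) had ITGA6 (-0.16, antisense partners), ITGA2 (-0.14), ITGB3 (0.12) and TNS3 (-0.11). Mesenchymal transition genes (13; adjusted p = 0.660) had VIM (-0.12, antisense partner), ZEB2 (-0.16) and SNAI1 (0.16). Guidance genes (22; adjusted p = 0.597) had EFNB1 (0.20), EFNA1 (0.22) and SEMA7A (-0.14). Over the 20 lists with 0 called genes, 0 to 7 members per list had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called at most 2 in any list and 0 in 14 of them. The sign of the median differed from that of the mean for Notch components, blood vascular, venous, G2/M, hypoxia and leukocyte genes. Camera compares test statistics per gene rather than fold changes. Its direction had the sign of the mean for these lists except venous and leukocyte genes, where it had the sign of the median.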

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

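The equal-depth version was chosen after seeing the data; all other alternatives were planned. Of 34 named genes that were called, 20 were called in each of up to 12 alternatives, SELE, CX3CL1, LTB, CCL2, TRAF1 and SOD2 among them. Against 83 higher and 17 lower genes, median-of-ratios factors gave 81 and 16, DESeq2 112 and 23, limma-voom 83 and 20, a mean of at least 1 CPM 76 and 16, and equal depth 80 and 16. With no low-count filter there were 140 and 42. The replicate block gave 34 and 6, of which 34 and 5 were shared with the fit without it. With the block, 21 of the 34 called named genes kept their call. Same-numbered libraries did not deviate together (correlations of -0.0896, -0.111 and -0.233). So few pairs cannot show whether same-numbered libraries shared a culture or day, so the block fit is not set aside. Leaving out single libraries gave 45 to 138 higher and 5 to 35 lower genes. Both highest counts came without Fc replicate 3, where the biological coefficient of variation dropped from 6.62% to 4.94%. Of lists, 5 were higher and 3 lower, with 3 to 5 and 2 to 4 on leaving out single libraries and 0 and 0 with an estimated correlation. At these depths genes at a few counts, such as HEY2 and CCL21, could not be tested.

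In all, 27 results changed sign in at least 1 alternative. None was called there, and 1 was called with all 6 libraries, the interferon list. The cause was not tested. With a mean of at least 1 CPM, adjusted p was 0.971 for Notch targets, 0.928 for Notch components and 0.799 for pericyte genes, and DLL4 was at 0.000199 in DESeq2. On leaving out single libraries, adjusted p ran from 0.518 to 0.998 for Notch targets, 0.523 to 0.959 for Notch components, 0.650 to 0.969 for blood vascular, 0.236 to 0.967 for venous, 0.266 to 0.827 for junction, 0.00165 to 0.988 for interferon, 0.385 to 0.901 for G1/S, 0.687 to 0.998 for hypoxia, 0.568 to 0.998 for VEGF, 0.202 to 0.969 for guidance, 0.0418 to 0.967 for fibroblast, 0.236 to 0.988 for pericyte and 0.525 to 0.969 for leukocyte genes. Log2 differences ran from -0.77 to 0.11 for FBLN1, -0.023 to 0.40 for COL3A1, -0.44 to 0.084 for CSF1R, -0.11 to 0.19 for CD74, -0.11 to 0.017 for NOTCH1, -0.16 to 0.16 for NOTCH2, -0.046 to 0.24 for NOTCH3, -0.059 to 0.040 for DLL4, -0.82 to 0.16 for HEYL, -0.084 to 0.066 for NRARP, -0.13 to 0.0054 for UNC5B, -0.028 to 0.020 for NR2F2, -0.0019 to 0.036 for CDH5 and -0.089 to 0.054 for PECAM1.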

Other observations

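The tests of Notch target activity, of an endotoxin-like stimulus and of other splits for the gene count were chosen after the result was seen. So were the genes named in the next 2 paragraphs, whose calls were not followed singly through the alternatives. Of the 83 higher genes, 22 were in the NF-kB or the adhesion and chemokine list and 57 were in no list.

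The colony-stimulating factor genes CSF1 and CSF3 rose on JAG1 by 0.50 and 2.88 on the log2 scale (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00101 and 0.000887), CSF3 from 0.206 CPM. The TNF family ligands TNFSF18 and TNFSF10 rose by 0.48 and 0.28 (adjusted p = 0.00104 and 0.0369), and the receptor gene TNFRSF4 by 0.57 (adjusted p = 0.0341). CD83 rose by 0.56 (adjusted p = 0.00846). TAP1, a peptide transporter gene of antigen presentation with an antisense partner, rose by 0.32 (adjusted p = 0.0280). RIPK2 (0.75), NFKBIZ (0.73), CEBPD (0.79) and POU2F2 (0.73) were also called higher.

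EDN1, the gene of the vasoconstrictor endothelin-1, rose on JAG1 by 0.46 on the log2 scale, ADM2 by 0.69, and F3, the tissue factor gene that starts coagulation, by 0.89 (adjusted p = 0.00399, 0.00399 and 0.0198). ACKR3, a scavenging receptor for chemokines and adrenomedullin, rose by 0.44 and RHOB, a GTPase gene of endothelial barrier control, by 0.59 to 935 CPM. KLF5, STC1 and MEF2C, which has an antisense partner, fell by 0.31, by 0.28 and by 0.24 (adjusted p = 0.0110, 0.0369 and 0.04998).

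The rise of NF-kB and chemokine genes was weighed against leukocyte RNA, lasting Notch target activity and a contaminant of the coating. Leukocyte-restricted transcripts summed to 2.03 CPM in Fc and 2.05 in JAG1 on average. They rose, at most, by 0.649 CPM between libraries, 0.0701% of the 926 CPM by which 22 called genes rose together. Leukocytes in the JAG1 cultures are thus an unlikely source of the summed rise. That sum rests largely on abundant genes such as SOD2 (385 to 705 CPM). It cannot decide the source for low genes such as CSF2 (0.130 to 2.39 CPM). Joint activity of HES1, HES4, HEY1 and NRARP at 6 h was bounded at 0.0918 on the log2 scale (upper 95% limit of a mean of 0.00881; 1.07-fold). This lay below 1.2-fold, a bound set after the genes' values were seen. The mean covers the genes jointly and lets opposite signs cancel. The upper limit of HES4 alone was 1.22-fold, above the bound, while those of HES1, HEY1 and NRARP lay below it. An earlier, ended activation was not tested. An endotoxin-like stimulus carried with the ligand stays open: interferon response genes had a median of 0.0715, and their list, called higher at adjusted p = 0.0402, stayed so in 5 of 10 alternatives, lost the call in 4 (adjusted p = 0.774 with an estimated correlation) and was lower, uncalled, without JAG1 replicate 3 (adjusted p = 0.988), short of a rise in every fit, and 2 groups cannot separate a ligand from its carrier. Signalling by the coated ligand, JAG1 per the titles or DLL4 per the protocol, also stays open as the biological explanation.

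The fall of keratin genes may reflect a few keratinocytes in the Fc cultures or a fall within the endothelial cells. A second list of 27 low keratinocyte genes was 1.56 times as high in Fc when summed, but 1.14 times between the closest libraries. The sum left the source undecided, because its members went different ways at low counts. KRT6B had 7, 11 and 12 counts in Fc and 0, 0 and 0 in JAG1. S100A14 had 11, 5 and 8 against 1, 2 and 3. LGALS7B had 6, 4 and 4 against 5, 4 and 7, and DSC3 had 7, 9 and 7 against 15, 3 and 5. RNA from several skin cell types also stays open: fibroblast and pericyte genes were 0.923 times as high in Fc as in JAG1, under the 1.5-fold bound set beforehand. That bound could not decide it, because their sum (17.3 ± 0.47 CPM in Fc and 18.7 ± 5.2 in JAG1, SD, n = 3 each) exceeded the 9.61 CPM by which KRT5, KRT14, KRT6A and KRT17 fell together, so a small share would be hidden (a comparison made after the values were seen).

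The lower mitochondrial genes could come from a lower share of mitochondrial RNA in general or from a wider fall of respiratory chain genes. The ribosomal genes MT-RNR1 and MT-RNR2 averaged -0.313 on the log2 scale, close to the median of -0.371 for the 13 coding genes, but neither was called (adjusted p = 0.799 and 0.534) and Fc replicate 3 stood far above the rest (MT-RNR2 at 9142 CPM against 4866 to 5897), so this cannot be told apart from no change in ribosomal RNA. The 76 nuclear respiratory chain genes had a median of 0.0452 (limits of 0.0292 to 0.0579 from a bootstrap over genes) and 0 were called. This argues against a wider fall in these libraries, although the limits leave out the spread between libraries. Whether RNA handling or the coating lowered mitochondrial RNA was not tested.

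The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 100 genes and the highest of the others 1, so 1 of 10 splits reached the real count. Every other split mixes JAG1 and Fc libraries, so a real difference would add to the spread within its groups. The low gene counts of the other splits therefore decide nothing. For gene lists the real split called 8 and the highest of the others 4, again with 1 of 10 splits reaching the real count. Several of the other splits called 1 or 4 lists, so list calls also arose where the groups were mixed.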
